A study of Takifugu obscurus with 9 samples.

How the data were processed

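RNA from whole kidney of obscure puffer was sequenced in 9 libraries, 3 labelled as controls at 0 h and 3 each from 12 h and 48 h after poly(I:C). Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates are separate fish, pools or repeated preparations, and they give no batch. The labels do not say whether the controls were injected, and none were sampled at 12 h or 48 h, so time after handling and treatment cannot be separated.

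The authors deposited 1 table of 46444 features with 9 value columns, each mapped to 1 library. The deposited values were taken to be TPM, although the header does not name the unit: the columns total 993873 to 996068, and low values fall on steps that shrink with feature length. Every feature exceeds 2 TPM in at least 1 library, the smallest such maximum being 2.01, so the table was filtered before deposit. Features are gene clusters of a de novo assembly, with a median length of 464 nucleotides. The assembler version, aligner and quantification tool are not stated, and no genome was used here. The table's own annotation gives a best protein match for 22968 features (49.45%), of which 21160 are to fish proteins, and a Swiss-Prot name for 18074. The table holds no counts. Depth was estimated from the step between low values of single-transcript features: 97.8% to 98.1% of those low values lay within 0.1 of a whole number of steps.

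Gene symbols for lists were assigned to features with a fish match only, first from the protein description through a table of usual protein names written before any test, and otherwise from the Swiss-Prot name. A symbol can therefore stand for a paralogue, and where several features carried 1 symbol the feature with the highest mean stood for the gene, which gave 11339 symbols.

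Features with at least 1 TPM in at least 3 libraries were kept (45473). Values were transformed as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 9 libraries, and moderated by eBayes with trend and robust options. The comparisons were 12 h against 0 h, 48 h against 0 h and 48 h against 12 h, each two-sided, and an F test over the 3 groups. A call is a Benjamini-Hochberg adjusted p under 0.05. The plan named count-based tests for read counts and limma for normalised values. With no read counts in the table, the limma branch was used, quantile normalization took the place of other size factors, and limma without the trend took the place of a second count-based test.

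The gene lists were fixed before the data were examined. They cover interferon-stimulated genes, RNA sensing, interferons with receptors and JAK-STAT, cytokines, MHC class I, MHC class II, complement, acute phase genes, apoptosis, cell cycle, heat shock and the unfolded protein response, glycolysis, cholesterol and steroid synthesis, oxidative phosphorylation, ribosomal proteins and the proteasome. Marker lists cover erythroid, B, T and NK, monocyte and macrophage, neutrophil, thrombocyte, proximal tubule, distal tubule, podocyte, interrenal and chromaffin, and endothelial cells, and muscle, liver and gut. Some genes belong to more than 1 list, such as cxcr2, stab2 and slc4a1. Lists were tested with camera in limma at a correlation of 0.01 between genes, adjusted over 84 tests, then with an estimated correlation and with fry. Ranges of a list's adjusted p over alternatives are of camera tests only, since fry tests a list against no change. Camera compares a list with the other genes, whose median log2 fold change over symbols was -0.0065, 0.175 and 0.195 in the 3 comparisons. Among lists that did not pass, camera's direction and the sign of the list's median differed in 3, 10 and 8 tests. Of the lists that passed, only the ribosomal proteins at 48 h against 0 h had a mean of the other sign.

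Named genes follow a rule fixed before the data were examined: for 12 h and 48 h against 0 h the 8 largest rises and 8 largest falls by fold change among called features with libraries that do not overlap between groups (a chance of 10% for 3 against 3), a mean of at least 5 TPM in the higher group and an informative name, for 48 h against 12 h the 5 largest each way, up to 2 features without a name each way, and up to 4 members of each list with the smallest adjusted p. Genes outside the rule are said to be chosen after their values were seen.

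Alternatives tried were quantile normalization, no trend, no filter, a filter of 5 TPM, a pseudocount of 0.1, the replicate number as a block, only the compared groups, leaving out each library, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and features summed by name. Chosen after seeing the data were averaging control libraries 1 and 2, doing so with 12 h library 3 left out, and keeping only features with a fish match. All 9 libraries were kept in the reported fit, including control libraries 1 and 2, which lie very close together, and 12 h library 3, which lies between its fellows. Where an alternative changed a sign while neither value was past the threshold, the result was counted as unchanged and the change of sign recorded. The fit was tested on simulated data with known changes of 50 features per size, all drawn from features with a mean of at least 5 TPM. Among these, 4-fold changes were recovered in 76%, 90% and 76% of cases in the 3 comparisons and 2-fold changes in 32%, 44% and 34%. Recovery among features with lower means was not tested. That test drew independent libraries, which the real ones may not be. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Features without a fish match were left out of list tests but kept in the counts of features.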

Results

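Whole kidney of 3-month-old obscure puffer (Takifugu obscurus) was profiled by RNA sequencing after a challenge with poly(I:C), a synthetic double-stranded RNA that vertebrate cells sense as they sense viral RNA. There were 9 libraries, with 3 taken at 0 h and labelled as controls, 3 at 12 h and 3 at 48 h. The fish kidney is both a renal organ and a blood-forming one, so it can hold transcripts of tubule, glomerular, red and immune cells. The deposited table gives values taken to be TPM, transcript abundance scaled to a common library total, for 46444 assembled features, a feature being a cluster of assembled transcripts treated as 1 gene. No read counts came with it. The steps between low values put the depth at an estimated 21200000 to 28100000 assigned reads per library, with 1 read worth 0.59 to 0.78 TPM on a feature of 250 nucleotides. Each library had between 32563 and 39551 features at 1 TPM or more, and its 10 most abundant features held 6.84% to 12.1% of the total. Of the features, 21160 had a best protein match in a fish and held 72.0% to 75.5% of the TPM, and 23476 had no protein match. Fold changes below are differences of log2(TPM + 1), and group values are mean TPM ± SD over 3 libraries. The p-values measure only the spread between these samples, which may be technical, since the labels do not say that each library came from a separate fish.

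The libraries did not form 3 even groups. Across features with a mean of at least 10 TPM, which are not independent replicates, the log2 values of control libraries 1 and 2 had a Pearson correlation of 0.985, against 0.879 to 0.967 for the other pairs within a group and 0.857 to 0.864 for control library 3 with either of them. Control library 3 was closer to the 48 h libraries, at 0.920 to 0.927. It held far more red cell and T cell message and less proximal tubule message than its fellow controls: the mean level of the erythroid list was higher by 1.5 log2 units, that of the T and NK cell list higher by 1.72, and that of the proximal tubule list different by -1.20. At the level of single genes, chosen after their values were seen, embryonic alpha globin (hbae) stood at 10565, 11288 and 35554 TPM in control libraries 1, 2 and 3, the T cell receptor component cd3e at 20.8, 19.2 and 147, and the muscle enzyme ckm at 0.15, 0.24 and 23.1. The antiviral gene rsad2 (viperin), chosen in the same way, stood at 2771 and 2924 TPM in control libraries 1 and 2 but at 310 in control library 3. It stood at 1303, 3564 and 2426 TPM at 12 h and at 99.3, 623 and 533 at 48 h. The 12 h library 3 lay between its fellows, close to a weighted mean of 12 h libraries 1 and 2 with weights of 0.45 and 0.55.

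**Figure D1:**
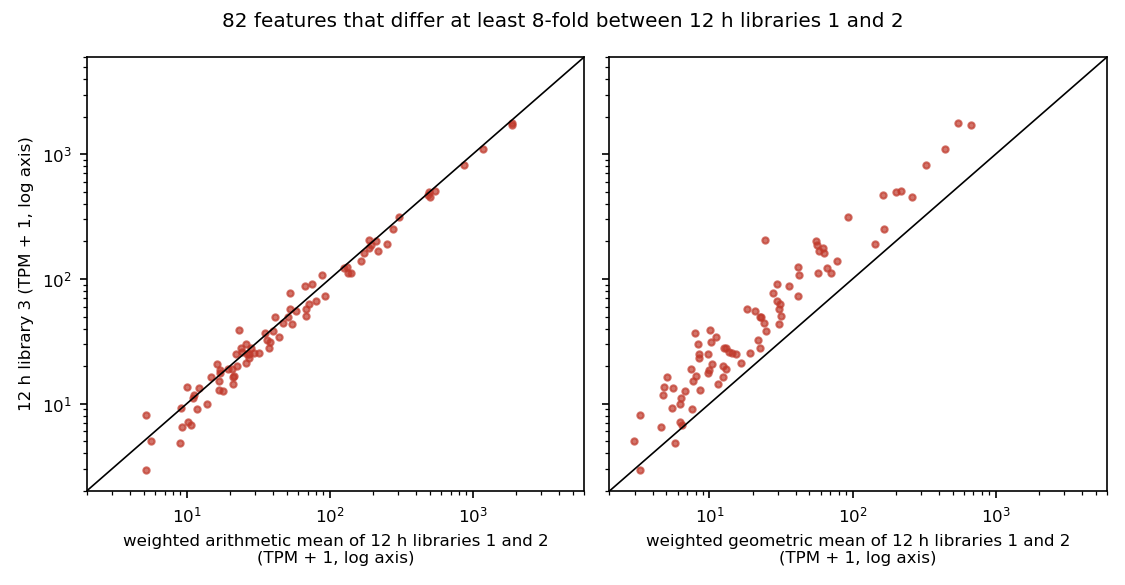
TPM + 1 of 82 features that differ at least 8-fold between 12 h libraries 1 and 2, in 12 h library 3 (vertical log axis) against the weighted arithmetic mean of libraries 1 and 2 (left, horizontal log axis) and their weighted geometric mean (right), with the line of equality. Library 3 lies closer to the arithmetic mean in 91.5% of the features. Both means use the weights that fit the arithmetic mean best, so the comparison leans towards it.

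**Figure D2:**
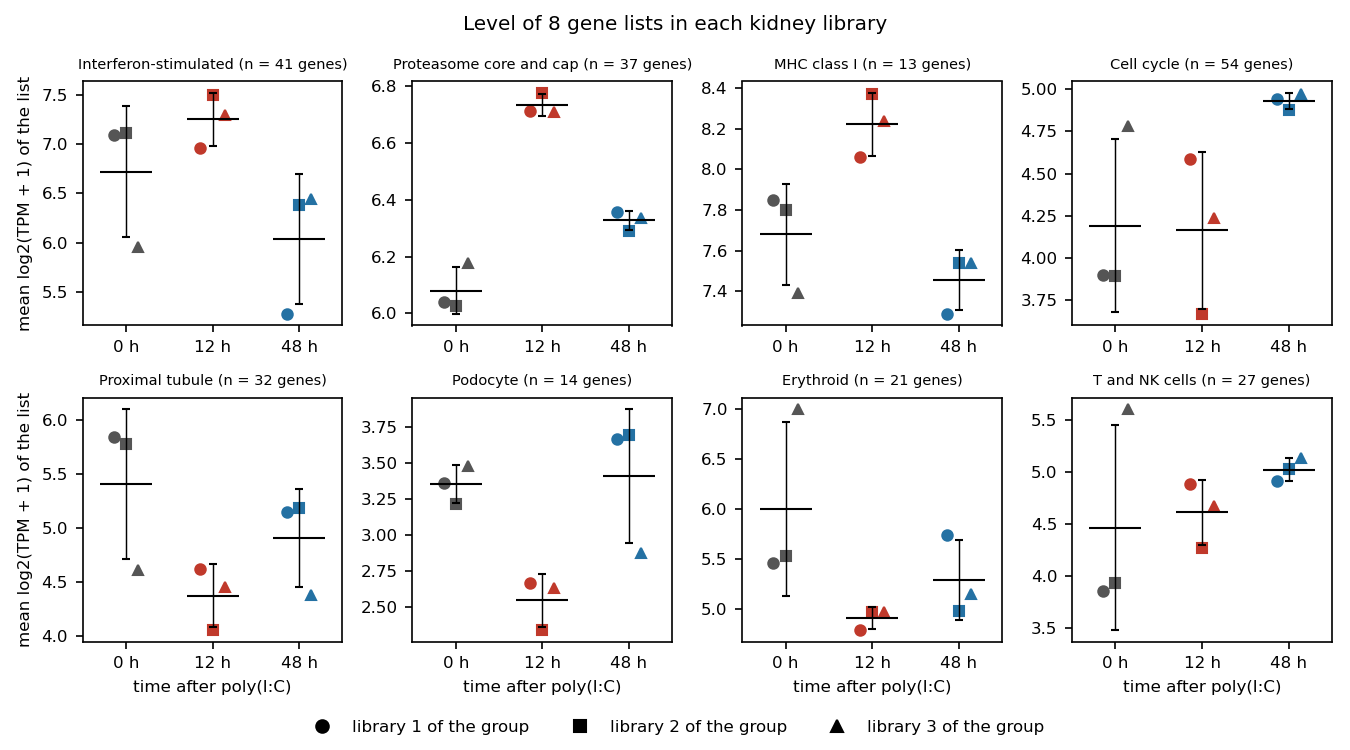
Mean log2(TPM + 1) of the genes of 8 lists in each kidney library at 0 h, 12 h and 48 h after poly(I:C). Points are libraries, horizontal lines are group means and error bars are SD over 3 libraries; proteasome genes lie at 6.08 ± 0.08 at 0 h, 6.73 ± 0.04 at 12 h and 6.33 ± 0.03 at 48 h, while control library 3 stands apart from the other controls in the erythroid and T and NK cell lists.

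The comparison of 12 h with 0 h asks which kidney transcripts differed 12 h after the challenge. GTPase IMAP family member 7 (gimap7), a lymphocyte GTPase, rose from 113 ± 71.7 to 1257 ± 598 TPM (log2 fold change 3.67, SE 0.58, limma adjusted p 0.0239). Its controls stood at 148, 160 and 30.2 TPM, and its call held in 5 of the 10 fits that left out 1 library or averaged control libraries 1 and 2, with an adjusted p of up to 0.116. The decoy receptor for interleukin 13, il13ra2, rose from 1.103 ± 0.728 to 23.3 ± 0.823 TPM, a change of 3.60 with adjusted p 0.00288. Ferroportin (slc40a1), the exporter that moves iron out of macrophages, fell from 81.9 ± 41.1 to 7.25 ± 3.83 TPM, a change of -3.34 with adjusted p 0.00883. In all, 269 features were higher and 378 lower out of 45473 tested, and 7231 had an unadjusted p under 0.05.

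Among the other features with the largest rises, one matching septin-1, a cytoskeletal GTPase, went from 0, 1.11 and 2.40 TPM in the controls to 320, 725 and 527 TPM. A feature for endonuclease domain-containing 1 protein rose from 5.96 ± 0.835 to 150 ± 91.5 TPM, and receptor-transporting protein 4, an interferon-induced antiviral factor in mammals, rose from 134 ± 73.2 to 1883 ± 1375 TPM with adjusted p 0.0491. The call of receptor-transporting protein 4 held in 1 of the 10 fits that left out 1 library or averaged control libraries 1 and 2, with a limma adjusted p of up to 0.185. Features matching a reverse transcriptase, phytanoyl-CoA dioxygenase domain-containing protein 1 and the ribosomal protein rps15 also rose, by 4.38, 3.38 and 3.50 log2 units. Summed over all features of the same description, rps15 was 859 TPM at 0 h and 840 TPM at 12 h, and the 28 reverse transcriptase features were 243 and 273 TPM, so those rises belong to single features. The 3 features of the dioxygenase description summed to 64.3 ± 27.7 TPM at 0 h and 95.8 ± 24.4 TPM at 12 h. The largest falls included the flavin monooxygenase fmo5, which went from 72.9 ± 19.6 to 6.52 ± 3.18 TPM, and a further feature of the same description, which fell by 3.75 log2 units. The intermediate filament gene vim fell from 17.2 ± 4.71 to 1.11 ± 0.755 TPM, and the organic anion transporter slc22a13, a lipocalin and the cysteine-rich secretory protein crisp2 had changes of -3.26, -3.48 and -3.55. The 17 features of the slc22a13 description summed to 372 ± 124 TPM at 0 h and 145 ± 46.6 TPM at 12 h. The controls stood at 10.06, 11.72 and 73.23 TPM for the lipocalin and at 51.93, 56.05 and 6.57 TPM for crisp2. The calls of these 2 held in 3 and 1 of the 10 fits that left out 1 library or averaged control libraries 1 and 2. One feature for interferon-induced protein 44 fell from 161 ± 65.3 to 1.02 TPM, whereas the sum of the 11 features of that description was 1541 ± 445 TPM at 0 h and 3406 ± 89.6 TPM at 12 h.

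The proteasome, the cell's protein-degrading complex, had more members past the threshold at 12 h than any other list tested. Of its 37 core and cap genes, 21 rose and none fell (31 rose adjusted over the list alone), with a median log2 fold change of 0.70. The alpha subunit gene psma3 rose from 131 ± 30.0 to 354 ± 14.9 TPM, the cap gene psmd8 from 55.6 ± 2.61 to 118 ± 1.42, psma1 from 141 ± 5.95 to 258 ± 5.16 and psmb3 from 96.4 ± 0.78 to 189 ± 20.3. The list ranked above other genes in the camera set test (adjusted p 1.44e-23, and adjusted p = 0.0983 with an estimated correlation). No proteasome gene passed without 12 h library 3, and 2 passed with control libraries 1 and 2 averaged. MHC class I presentation ranked above other genes as well (adjusted p 2.88e-06, and adjusted p = 0.319 with an estimated correlation), with 1 of 13 genes past the threshold and 9 adjusted over the list alone. The proteasome activator psme1 rose by 0.87 log2 units, and the immunoproteasome genes psmb9 and psmb8 and the peptide transporter tap1 had changes of 0.70, 0.53 and 1.13 with adjusted p of 0.0696, 0.0725 and 0.0811. Heat shock and unfolded protein response genes ranked higher (adjusted p 5.27e-06, and adjusted p = 0.368 with an estimated correlation), with 1 of 30 past the threshold by either adjustment, the chaperone hspa4 at 0.998 log2 units. Apoptosis genes ranked higher (adjusted p 0.0202, and adjusted p = 0.319 with an estimated correlation), with 2 of 30 past the threshold and 2 adjusted over the list alone: the cell cycle inhibitor cdkn1a rose by 1.34 and the initiator caspase casp8 by 1.23. That list's camera adjusted p was 0.0524 without 12 h library 2 and 0.0658 after quantile normalization, in a range of 0.00803 to 0.319 over its alternatives.

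Interferon-stimulated genes, the antiviral effectors switched on by interferon, ranked above other genes (adjusted p 8.68e-04, and adjusted p = 0.731 with an estimated correlation), with 2 of 41 past the threshold and 4 adjusted over the list alone. The gene ifi44l rose from 129 ± 15.6 to 632 ± 141 TPM and parp14 from 121 ± 10.5 to 208 ± 8.92, while rnf213a and ifi35 had changes of 1.13 and 0.74 with adjusted p of 0.0713 and 0.0737. The calls of ifi44l and parp14 held in 3 and 1 of the 10 fits that left out 1 library or averaged control libraries 1 and 2. Without 12 h library 3, or with that control pair averaged, 0 members of the list passed. The list's mean level was 6.72 ± 0.66 at 0 h and 7.25 ± 0.27 at 12 h, and control library 3 differed from its fellow controls by -1.15. Without control library 3 the list's adjusted p was 0.487 and without 12 h library 2 it was 0.0702, in a range of 3.26e-06 to 0.731 over its alternatives. Interferons with their receptors and JAK-STAT genes did not pass (adjusted p 0.118), nor did RNA sensing genes (adjusted p 0.207), of which the flagellin receptor tlr5 fell by 1.08 log2 units. The JAK-STAT list ranked above other genes with adjusted p 0.00490 without 12 h library 1, 0.0400 and 0.0378 without control library 1 or 2, 0.0371 with those averaged and 0.0355 with 12 h library 3 left out as well. The RNA sensing list did so with 0.00918 without 12 h library 1. Of 36 cytokines, chemokines and inflammatory mediators, 2 rose and 3 fell (3 and 3 adjusted over the list alone), and the list did not pass (adjusted p 0.435). The anti-inflammatory cytokine il10 rose from 11.7 ± 4.81 to 58.1 ± 18.7 TPM and the eosinophil chemokine receptor ccr3 by 2.10 log2 units. The neutrophil receptor cxcr2 fell from 29.1 ± 6.04 to 5.90 ± 1.44 TPM and its ligand cxcl8 from 189 ± 91.3 to 38.7 ± 6.45. That cxcl8 call held in 2 of the 10 fits that left out 1 library or averaged control libraries 1 and 2. A second feature for cxcl8 stood at 66.2 ± 8.70 TPM at 0 h and 43.6 ± 6.48 at 12 h. Of 15 acute phase, iron and antimicrobial genes (adjusted p 0.517), bpi, whose product kills bacteria, rose by 1.72 log2 units, and slc40a1 and the ferritin gene ftl fell (4 rose and 4 fell adjusted over the list alone). Without 12 h library 2 that list ranked lower with adjusted p 0.0141.

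Lists of renal cell markers ranked lower. Proximal tubule genes, which recover solutes from the filtrate, ranked below other genes (adjusted p 2.05e-06, and adjusted p = 0.54 with an estimated correlation), with 3 of 32 past the threshold and 10 adjusted over the list alone. The count of 3 ran from 0 to 12 when 1 library was left out, with 0 without 12 h library 3, and was 0 with control libraries 1 and 2 averaged. The protein uptake gene amn fell from 14.5 ± 4.60 to 2.22 ± 0.129 TPM, the brush border peptidase anpep by 3.13 log2 units and the water channel aqp1 by 1.60. The control libraries were themselves uneven here, control library 3 differing from its fellows by -1.20 log2 units and lying within the 12 h libraries. Podocyte and glomerulus genes ranked lower (adjusted p 3.04e-04, and adjusted p = 0.464 with an estimated correlation), with 1 of 14 past the threshold and 6 adjusted over the list alone. The surface protein gene podxl fell by 1.74 log2 units, and nephrin (nphs1) had a change of -1.37 with adjusted p 0.0549. Distal tubule genes ranked lower with none of 19 past the threshold by either adjustment (adjusted p 0.0202, and adjusted p = 0.615 with an estimated correlation). Control library 3, different from its fellows by -0.67 log2 units, already lay at the 12 h level in that list. Its adjusted p was 0.123 without control library 1 or without control library 2 and 0.052 without 12 h library 1, in a range of 1.71e-04 to 0.615 over its alternatives.

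Erythroid genes ranked lower (adjusted p 2.11e-06, and adjusted p = 0.54 with an estimated correlation), with a median of -1.16 and 1 of 21 past the threshold, the transcription factor tal1 at -1.53 (10 fell adjusted over the list alone). Control library 3 carried the high erythroid level given above. Monocyte, macrophage and dendritic cell genes ranked lower (adjusted p 0.0148, and adjusted p = 0.462 with an estimated correlation). Of these 21 genes, the growth factor receptor csf1r fell by 1.77 log2 units and the mannose receptor mrc1 by 0.87, while galectin-3 (lgals3) rose by 0.70 (8 fell and 2 rose adjusted over the list alone). Without 12 h library 1 the list's adjusted p was 0.0503, in a range of 0.00336 to 0.462. Muscle, liver and gut genes ranked lower (adjusted p 0.0268, and adjusted p = 0.308 with an estimated correlation), with the lipase cel falling by 1.45 log2 units (3 of 18 fell adjusted over the list alone). Their camera adjusted p was 0.122 without 12 h library 1, 0.132 with no filter and 0.106 with features summed by name, in a range of 0.00151 to 0.308. Control library 3 was higher in this list than its fellow controls by 0.57 log2 units. MHC class II genes did not pass (adjusted p 0.066), although 2 of 12 fell (3 adjusted over the list alone), among them the beta chain gene dab by 0.70 log2 units. That list ranked lower with adjusted p 0.0205 after quantile normalization, 0.0309 without control library 3 and 0.0219 without 12 h library 2. T and NK cells (adjusted p 0.328), B and plasma cells (0.909), neutrophils (0.241), thrombocytes (0.263), endothelium (0.185), interrenal and chromaffin cells (0.152) and complement (0.329) did not pass. Without control library 3 the T and NK cell list ranked above other genes with adjusted p 1.18e-05.

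Metabolic lists did not pass at 12 h, although some members changed. Of 19 glycolysis genes (adjusted p 0.909), the glucose transporter slc2a1 fell from 15.9 ± 0.301 to 6.78 ± 0.261 TPM and gapdh by 2.43 log2 units, while glucokinase (gck) rose by 2.14. Of 88 oxidative phosphorylation genes (adjusted p 0.33), the assembly factor sdhaf3 fell by 1.52 log2 units. Ribosomal protein genes (adjusted p 0.33), cholesterol and steroid synthesis genes (0.966) and cell cycle genes (0.749) did not pass. Cell cycle genes ranked higher with adjusted p 0.00406 without control library 3 and 0.0141 without 12 h library 2, and oxidative phosphorylation genes with 0.00721 without 12 h library 2. Ribosomal protein genes ranked lower with 0.00904 after quantile normalization and 0.00803 without 12 h library 1.

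The number of features called at 12 h rested on a few libraries: it was 34 without 12 h library 3, 95 without 12 h library 2, 50 and 55 without control library 1 and control library 2, 60 with those control libraries averaged and 3 with both steps together. It was also 230 without the trend in limma, 250 with only the compared groups, 284 with the replicate number as a block and 61 at adjusted p under 0.01. Of the 52 named features past the threshold, 11 passed in every fit that left out 1 library or averaged the control pair, among them il13ra2, fmo5, slc22a13, vim, cxcr2 and the septin-1 and endonuclease domain-containing 1 features. Leaving out 12 h library 3 ended the call of 40 of the 52, and leaving out 12 h library 2 that of 32, control library 1 or 2 that of 38, control library 3 that of 14, 12 h library 1 that of 13 and 48 h libraries 1, 2 and 3, which share the fit, that of 11, 19 and 12.

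**Figure D3:**
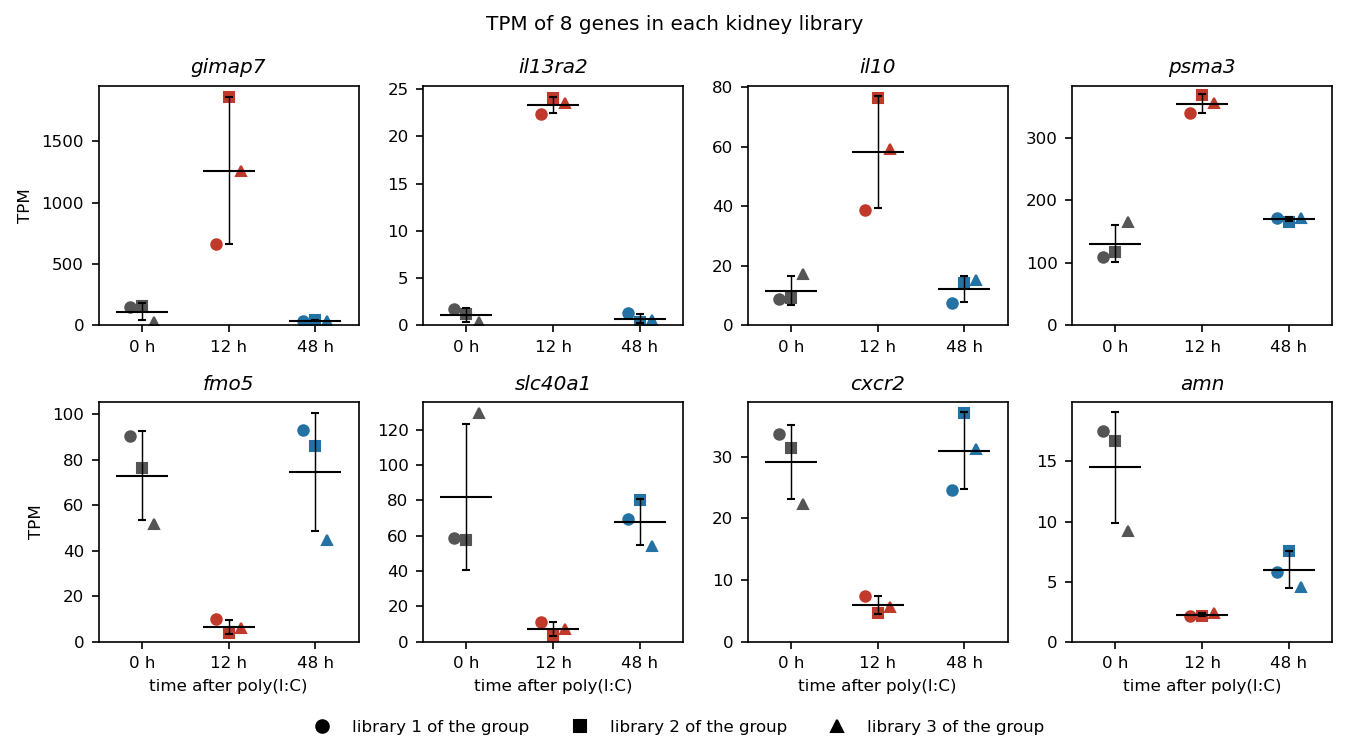
TPM of 8 genes in each kidney library at 0 h, 12 h and 48 h after poly(I:C), with group means as horizontal lines and SD over 3 libraries as error bars. The immune genes gimap7, il13ra2 and il10 and the proteasome gene psma3 are highest in the 12 h libraries, at group means of 1257, 23.3, 58.1 and 354 TPM, and fmo5, slc40a1, cxcr2 and amn are lowest there, at 6.52, 7.25, 5.90 and 2.22 TPM.

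**Figure D4:**
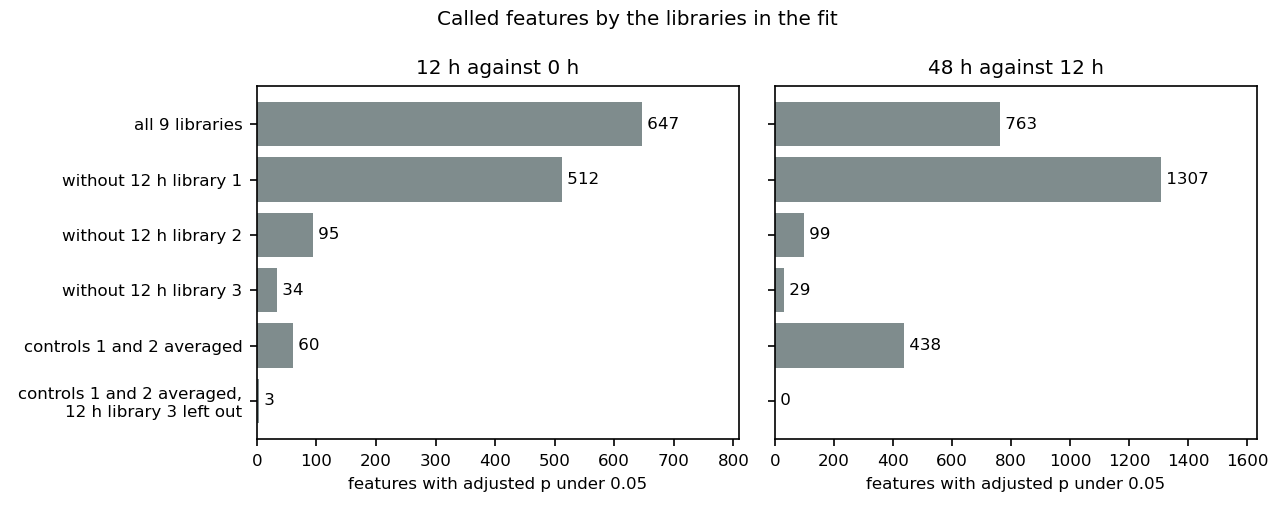
Number of features with a limma adjusted p under 0.05 at 12 h against 0 h and at 48 h against 12 h, with all 9 libraries, without each 12 h library, with control libraries 1 and 2 averaged, and with that step plus 12 h library 3 left out. The counts run from 3 to 647 and from 0 to 1307.

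The comparison of 48 h with 0 h asks what differed from the controls 48 h after the challenge. Very few single features did: 4 were higher and 1 was lower by limma, and 5038 had an unadjusted p under 0.05. The septin-1 feature rose to 85.6, 86.9 and 177 TPM in the 48 h libraries (log2 fold change 5.84, SE 0.47, adjusted p 0.00789). The rps15 feature rose by 3.38 log2 units, from 4.23 to 54.1 TPM, while all rps15 features summed to 839 TPM. The others that rose were an uncharacterized protein and a feature with no protein match, by 4.54 and 2.82 log2 units. The second feature for cxcl8, the neutrophil-attracting chemokine, fell from 66.2 ± 8.70 to 16.02 ± 2.17 TPM (log2 fold change -1.98, SE 0.17, adjusted p 0.00789).

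At 48 h 13 gene lists passed by camera at a correlation of 0.01 between genes, but 0 passed with an estimated correlation and 2 of the 13 by fry. The estimated correlation was 0.779 for the cell cycle list and 0.527 for the interferon-stimulated list. A broad difference of lists therefore rests on the low correlation that was set. No member of any list passed over all features by the feature that stood for it. Cell cycle and DNA replication genes ranked above other genes (adjusted p 1.05e-08, and adjusted p = 0.599 with an estimated correlation), with 53 of 54 higher, a median of 0.73 and none past the threshold adjusted over the list alone. The mitotic cyclin ccnb1 was 99.4 ± 47.3 TPM at 0 h and 198 ± 10.8 at 48 h, and the mitotic kinesin kif20a was 13.95 ± 5.50 and 34.5 ± 2.25. Control library 3 had a higher cell cycle level than the other controls by 0.88 log2 units. The T and NK cell list varied with it over the libraries, at 3.86, 3.93 and 5.61 in the controls and 4.92 to 5.14 at 48 h; the cell cycle list was likewise higher in control library 3 (4.78) and at 48 h (4.88 to 4.97) than in the other controls. Proteasome genes still ranked higher (adjusted p 0.00139, and adjusted p = 0.464 with an estimated correlation), with a median of 0.28 and psmb5 at 71.5 ± 7.14 and 106 ± 12.4 TPM. Interferon-stimulated genes ranked below other genes (adjusted p 5.82e-13, and adjusted p = 0.456 with an estimated correlation), with 36 of 41 lower than at 0 h and a median of -0.70. The E3 ligase trim25 was 293 ± 108 TPM at 0 h and 136 ± 72.3 at 48 h, and parp12 was 356 ± 150 and 147 ± 78.3. The interferon list differed among the controls by the -1.15 log2 units given for control library 3, and 48 h library 1 lay lowest at 5.27 against 6.38 and 6.44. RNA sensing genes ranked lower (adjusted p 0.0148, and adjusted p = 0.615 with an estimated correlation), with the helicase ifih1 at 158 ± 86.1 and 63.6 ± 30.8 TPM. Their median was -0.014, with 21 members higher and 22 lower, beside a median of 0.175 over all symbols. Without 48 h library 1 the RNA sensing list had adjusted p 0.313, in a range of 1.35e-04 to 0.615 over its alternatives. Cytokines ranked lower (adjusted p 4.43e-04, and adjusted p = 0.197 with an estimated correlation), with the inflammatory cytokine tnf at 11.8 ± 5.34 and 3.27 ± 1.45 TPM. Control library 3 already lay within the 48 h libraries in the interferon-stimulated, RNA sensing and cytokine lists, different from its fellows by -0.33 and -0.40 log2 units in the last pair. Those lower ranks against 0 h therefore rest on control libraries 1 and 2.

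Antigen presentation and the renal and red cell lists also ranked lower at 48 h. MHC class II genes had adjusted p 3.23e-05, and adjusted p = 0.0983 with an estimated correlation, with 3 of 12 lower adjusted over the list alone and dab at 905 ± 60.9 TPM at 0 h and 539 ± 34.2 at 48 h. MHC class I genes had adjusted p 1.77e-04, and adjusted p = 0.368 with an estimated correlation, with beta-2-microglobulin (b2m) at 5098 ± 465 and 4066 ± 116 TPM. Proximal tubule genes had adjusted p 2.91e-08, and adjusted p = 0.534 with an estimated correlation. Of these, amn was 5.97 ± 1.54 TPM at 48 h, and the inositol enzyme miox, at 38.2, 40.6 and 0.6 TPM in the controls, was 0.64 ± 0.191. Distal tubule genes had adjusted p 1.51e-07, and adjusted p = 0.361 with an estimated correlation, with uromodulin (umod) at 84.2, 81.6 and 8.45 TPM in the controls and 6.72 ± 6.84 at 48 h. Control library 3 lay within the 48 h libraries in the MHC class I, proximal tubule and distal tubule lists, different from its fellows by -0.43, -1.20 and -0.67 log2 units. These changes too rest on control libraries 1 and 2. Erythroid genes had adjusted p 5.83e-08, and adjusted p = 0.534 with an estimated correlation, with 4 of 21 lower adjusted over the list alone, the globin genes hba, hbae and hbb1 and the heme enzyme alas2. Without control library 3 the erythroid list had adjusted p 0.132, in a range of 7.65e-16 to 0.534. Acute phase genes had adjusted p 3.04e-04, and adjusted p = 0.197 with an estimated correlation, with C-reactive protein (crp) at 104 ± 33.8 and 49.1 ± 2.17 TPM. Muscle, liver and gut genes had adjusted p 5.68e-04, and adjusted p = 0.133 with an estimated correlation; control library 3 was higher in this list by 0.57 log2 units. Ribosomal protein genes ranked lower (adjusted p 0.00238, and adjusted p = 0.8 with an estimated correlation), with a median of -0.006 and a mean of 0.02. They ranked above other genes after quantile normalization (adjusted p 0.986), had adjusted p 0.646 without 48 h library 2, and ranged from 4.69e-06 to 0.986 over the alternatives.

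Other lists did not pass at 48 h, with adjusted p of 0.866 for T and NK cells, 0.132 for B and plasma cells, 0.687 for monocytes and macrophages, 0.356 for neutrophils, 0.477 for thrombocytes, 0.786 for endothelium, 0.361 for podocytes, 0.508 for interrenal and chromaffin cells, 0.234 for complement, 0.132 for interferon receptors and JAK-STAT, 0.755 for apoptosis, 0.615 for heat shock genes, 0.749 for glycolysis, 0.615 for cholesterol synthesis and 0.316 for oxidative phosphorylation. In the neutrophil list, 4 of 16 genes were higher adjusted over the list alone. Without control library 3 the T and NK cell list ranked above other genes at 48 h with adjusted p 1.52e-04. Neutrophil genes ranked higher without control library 1 (0.0413), and oxidative phosphorylation genes without 48 h library 2 or 3 (0.0317). Lists that ranked lower with 1 library left out were B and plasma cells (0.0115 without 48 h library 3) and JAK-STAT genes (0.0287 without control library 3 and 0.0203 without 48 h library 3). The 5 called features became 78 without control library 3, 1 without control library 1, 2 without 48 h library 1, 0 without 48 h library 3 (by limma), 0 without the trend in limma, and 3 with a pseudocount of 0.1, a replicate block, summed features or adjusted p under 0.01. With control libraries 1 and 2 averaged and 12 h library 3 left out, 0 features were called.

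The comparison of 48 h with 12 h asks what changed between the sampling times. The gene gimap7 fell from 1257 ± 598 to 40.3 ± 2.06 TPM (log2 fold change -4.81, SE 0.58, limma adjusted p 0.0102), il13ra2 from 23.3 ± 0.823 to 0.733 ± 0.518 TPM, and receptor-transporting protein 4 and the endonuclease domain-containing 1 feature had changes of -4.73 and -4.51. The genes fmo5 and slc40a1 rose to 74.5 ± 26.0 and 67.9 ± 13.1 TPM, by 3.34 and 3.16 log2 units, vim by 3.35, the lipocalin by 3.64 and the further monooxygenase feature by 3.60. The reverse transcriptase and rps15 features that rose at 12 h went from 63.0 and 57.9 TPM to 71.3 and 54.1 TPM. The galectin-3-binding protein gene lgals3bpa fell from 374 ± 163 to 27.5 ± 25.5 TPM, against 245 ± 47.7 at 0 h. In all, 485 features were higher and 278 lower, with 9768 at an unadjusted p under 0.05. Of the 763, 319 were also called at 12 h against 0 h, all in the opposite direction, which the shared 12 h libraries favour without any return towards 0 h. After quantile normalization, which moved the median fold change of all features by -0.18, 264 were higher and 358 lower.

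Of 41 interferon-stimulated genes, 5 fell and none rose (24 fell and 2 rose adjusted over the list alone), with a median of -1.27. The gene rnf213a fell from 435 ± 44.9 to 148 ± 44.3 TPM, ifi44l by 2.10 log2 units, parp14 by 0.98 and ifi35 by 0.96. The list ranked below other genes (adjusted p 4.31e-17, and adjusted p = 0.368 with an estimated correlation). For rsad2 and the antiviral GTPase mx1, both chosen after their values were seen, the changes were -2.80 and -2.74 with adjusted p of 0.127 and 0.0588. MHC class I genes ranked lower (adjusted p 2.32e-11, and adjusted p = 0.184 with an estimated correlation), with 6 of 13 falling and 10 adjusted over the list alone. Of these, b2m fell by 0.71 log2 units, psme1 by 1.06 and tap1 by 1.60. Proteasome genes ranked lower (adjusted p 9.61e-19, and adjusted p = 0.0983 with an estimated correlation), with 8 of 37 falling and 23 adjusted over the list alone. Of these, psmd8 fell to 64.2 ± 3.82 TPM, psma3 to 170 ± 3.61, psmb3 to 112 ± 5.89 and the beta subunit gene psmb1-a to 164 ± 10.5. No member of these 3 lists passed without 12 h library 3.

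Signalling and stress lists ranked lower too. Cytokines (adjusted p 3.95e-04, and adjusted p = 0.197 with an estimated correlation) had 2 of 36 fall and 1 rise, with 7 and 4 adjusted over the list alone. In that list il10 fell by 2.16 log2 units, the dendritic cell homing receptor ccr7 fell by 1.15 and cxcr2 rose by 2.21. RNA sensing genes (adjusted p 8.68e-04, and adjusted p = 0.54 with an estimated correlation) had tlr5 rise by 1.42 as the 1 member of 43 past the threshold, by either adjustment. JAK-STAT genes (adjusted p 0.00840, and adjusted p = 0.54 with an estimated correlation) had 5 of 27 lower adjusted over the list alone, with the feedback inhibitor socs3 at 167 ± 125 TPM at 12 h and 26.0 ± 1.73 at 48 h. The median of the JAK-STAT genes was -0.008, with 13 higher and 14 lower. Without 12 h library 2 or 48 h library 1 their adjusted p was 0.0634 or 0.0533, in a range of 4.67e-04 to 0.54. Heat shock genes (adjusted p 3.42e-06, and adjusted p = 0.368 with an estimated correlation) had 6 of 30 lower adjusted over the list alone. Apoptosis genes (adjusted p 0.0202, and adjusted p = 0.319 with an estimated correlation) had casp8 fall by 1.39 and cdkn1a by 0.98 (7 fell and 3 rose adjusted over the list alone), and had adjusted p 0.0648 after quantile normalization, in a range of 0.00951 to 0.319. The median of the apoptosis genes was -0.029, with 15 higher and 15 lower. Interrenal and chromaffin genes (adjusted p 0.0492, and adjusted p = 0.604 with an estimated correlation) had 1 of 9 higher and 1 lower adjusted over the list alone. Their adjusted p was over the threshold in most other fits, at 0.523 without 12 h library 1, 0.218 without 48 h library 2, 0.126 without control library 1, 0.114 without 12 h library 3, 0.10 without 48 h library 1, 0.0598 without control library 3 and 0.0505 without control library 2, in a range of 0.0110 to 0.604.

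Cell cycle and glomerular genes ranked higher at 48 h. The cell cycle list (adjusted p 8.84e-05, and adjusted p = 0.731 with an estimated correlation) had none of 54 past the threshold and 27 higher adjusted over the list alone, with the spindle motor kif11 at 22.5 ± 7.88 and 58.2 ± 2.43 TPM. The 12 h libraries were uneven in this list, with an SD of 0.46 log2 units. Podocyte genes (adjusted p 0.00955, and adjusted p = 0.54 with an estimated correlation) had nphs1 rise by 1.64 and podxl by 1.62, with 7 of 14 adjusted over the list alone, and had adjusted p 0.064 without 48 h library 1, in a range of 3.28e-05 to 0.54. Monocyte and macrophage genes did not pass as a list (adjusted p 0.152), but 4 of 21 rose (12 rose and 1 fell adjusted over the list alone), among them mrc1 by 0.92, the scavenger receptor stab2 by 2.70, csf1rb by 1.30 and the complement gene c1qc by 1.63. That count of 4 ran from 0 to 10 when 1 library was left out, with 0 without 12 h library 3, and was 2 with the control pair averaged. In lists that did not pass, the lysozyme gene lyg fell from 1341 ± 737 to 202 ± 16.4 TPM, bpi by 2.37 log2 units, gck by 2.33, the T cell genes cd28 by 1.71 and tcf7 by 1.20, while rhag rose by 1.64, sdhaf3 by 1.59, fbp1 by 0.998 and pmvk by 1.02. The adjusted p of those lists were 0.152 for acute phase genes, 0.964 for glycolysis, 0.597 for T and NK cells, 0.615 for erythroid, 0.928 for oxidative phosphorylation, 0.514 for proximal tubule and 0.817 for cholesterol synthesis. Those of the rest were 0.182 for distal tubule, 0.204 for B cells and for endothelium, 0.263 for ribosomal proteins and for MHC class II, 0.638 for thrombocytes and for muscle, liver and gut, 0.866 for neutrophils and 0.966 for complement. Some of these lists passed in other fits. Acute phase genes ranked lower with no filter (0.00195) and distal tubule genes lower without 48 h library 1 (0.0294). Proximal tubule genes ranked higher without 48 h library 3 (0.0338), and monocyte genes after quantile normalization (0.0167) and without 12 h library 2 (0.0339). Ribosomal proteins ranked lower without 12 h library 2 (0.0110) or 48 h library 1 (0.0140), but higher after quantile normalization (0.0135).

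The count at 48 h against 12 h was 29 without 12 h library 3, 99 without 12 h library 2, 1307 without 12 h library 1, and 289, 56 and 192 without 48 h libraries 1, 2 and 3. It was 438 with control libraries 1 and 2 averaged and 0 with 12 h library 3 left out as well, where 6784 features still had an unadjusted p under 0.05 by limma, 326 without the trend, 285 with a replicate block, 1364 with a filter of 5 TPM, 1559 over features with a fish match and 35 at adjusted p under 0.01. Of the 50 named features past the threshold, 7 passed in every one of the 10 fits that left out 1 library or averaged the control pair, among them il13ra2, fmo5, vim and cxcr2. The call ended without 12 h library 3 for 40 of the 47 that could be tested there, without 12 h library 2 for 35 and without 12 h library 1 for 2. It ended without 48 h libraries 1, 2 and 3 for 27, 40 and 28 of the 50, and without control libraries 1 and 2 for 13 and 15.

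Over the 3 groups together the limma F test called 536 features, with 9190 at an unadjusted p under 0.05. The responses at 12 h and 48 h share their controls, so their fold changes correlate without any shared response. The correlation across features, which are not independent replicates, was 0.346, against 0.50 in 20 simulations of unchanged groups with the same controls, and the covariance was 0.119 against a simulated 0.109 (0.106 to 0.111). Leaving out 1 library, for which no simulation was run, moved the correlation between 0.282 and 0.522 and the covariance between 0.102 and 0.249, the highest of each without control library 3. There were 4 features higher at both times. Independent lists give 0.0237 on average, a value that leaves out the shared controls, and the simulations gave none, a value that leaves out the effects, so neither shows that the 4 are a shared response, and part of any excess may come from the shared controls. That count of 4 was 0 without the trend in limma and ran from 0 to 33 when 1 library was left out.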

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

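Tests of a shared RNA sample, of a mixture, of a response of intermediate size and of the share of renal RNA, and the proteasome list and held-out libraries in the tests of labels, were chosen only after the result was seen, while the splits and the first form of both tests of labels were planned before. The tests of the 12 h label and of the renal share also changed form after values were seen: an earlier condition on quartiles left the 12 h label of control libraries 1 and 2 undecided, since their upper quartiles of 0.516 and 0.512 overlap a lower quartile of 0.372 in 12 h library 1; the prediction interval replaced a bound of 3 SD, with the same label; and an earlier renal test, with a standard error over genes (erythroid median -1.16, standard error 0.148), had argued against a smaller renal share.

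The effects of 12 h and 48 h against the same controls differed in a direct test of 48 h against 12 h, in 763 features and in 11 gene lists. The lists' camera adjusted p were 9.61e-19 for the proteasome, 4.31e-17 for interferon-stimulated genes, 2.32e-11 for MHC class I, 3.42e-06 for heat shock, 8.84e-05 for the cell cycle, 3.95e-04 for cytokines, 8.68e-04 for RNA sensing, 0.00840 for JAK-STAT, 0.00955 for podocytes, 0.0202 for apoptosis and 0.0492 for interrenal cells. None of these lists passed with an estimated correlation. The 10 splits of 6 libraries are too few for a share under 0.05. At 48 h against 12 h the real split gave 763 features and the highest other 0, at 12 h against 0 h 647 and 1, and at 48 h against 0 h 5 and 58. Counting the real split itself, 1, 1 and 2 splits were as large. Over the 3 groups, 2 of 100 splits, the real one with 536 features included, gave as many, and the highest other gave 924. That share under 0.05 excludes chance only if the 9 libraries are independent. With control libraries 1 and 2 averaged and 12 h library 3 left out the same F test called 3 features. The split that gave 924 put control libraries 1 and 2 with a 48 h library and control library 3 with the other 48 h libraries, and so left the 12 h libraries together. It points to a structure among the controls.

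The first pattern is that control libraries 1 and 2 lie together and apart from control library 3: over features with enough estimated reads, the difference between the pair was 1.47 times that of counting noise by the median chi-square, against 4.92 for the next closest pair within a group, and the mean chi-square of 3.29 is above noise, so 1 RNA sample behind both may account for the pair but cannot be told apart from 2 very similar fish. Control libraries 1 and 2 lay away from the 12 h libraries, but this does not exclude that they are mislabelled 12 h libraries. In the proteasome list, the first by p in the comparison of 48 h with 12 h, they lay at 6.04 and 6.03, against 6.71, 6.78 and 6.71 at 12 h. Between 48 h (0) and 12 h (1) that is -0.71 and -0.75, and it is outside the 95% prediction interval of 6.54 to 6.92 for a further 12 h library. That interval takes the 12 h libraries as 3 independent ones, which 12 h library 3 may not be, and the list was picked from a comparison of those same libraries. Over 756 features the median positions of control libraries 1 and 2 were 0.288 and 0.285, under the planned bound of 0.3 by less than their spread over features. That control library 3 is a mislabelled 48 h library was not decided: just 1 feature met the planned criterion, with 0% in the 48 h range, and over 47, 43 and 17 features called between the other controls and a pair of 48 h libraries its median position was 1, 0.784 and 0.989 between those controls (0) and the pair (1), beside 0.766, 0.727 and 0.931 for the 48 h library left out, as features that set control libraries 1 and 2 apart from other fish would give too. Against that label, all 5 features called at 48 h against 0 h put library 3 with the controls, such as septin-1 at 2.40 TPM against 85.6 to 177 and rps15 at 2.52 against 33.2 to 67.4, and its proteasome level of 6.18 is below every 48 h library, outside a bound of 3 SD tried first but inside the 95% prediction interval from 6.16; yet those calls counted it as a control, and of the 47, 43 and 17 features chosen without it 8, 5 and 1 stayed near the other controls, against 4, 4 and 0 in the 48 h library left out. On 25 interferon genes, picked as lower at 48 h than at 12 h by over 1 log2 unit, control libraries 1 and 2 had median positions of 0.915 and 0.948 between 48 h (0) and 12 h (1). Control library 3 stood at -0.061 on that scale. Prior stimulation or infection of the fish behind control libraries 1 and 2 therefore stays open and untested.

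The second pattern is that 12 h library 3 lies between 12 h libraries 1 and 2. Over 82 features that differ at least 8-fold between those libraries, library 3 was closer to their weighted arithmetic mean in 91.5%, the mean that mixed RNA or reads would give. A response of intermediate size in every cell was taken to need most of them closer to the geometric mean, and 8.54% were. Both means used the weights of 0.45 and 0.55 chosen for the arithmetic mean, and none were fitted for the geometric mean. The comparison therefore leans towards the arithmetic mean. Yet library 3 lay mostly above the geometric mean, whichever of libraries 1 and 2 was higher. A feature at 31.7 and 876 TPM in them stood at 498 in library 3, against a geometric mean of 199. Another at 94.4 and 6.83 TPM stood at 43.0, against 23.1. Another weight would bring either kind closer only by moving the other away. This argues against a response at 1 common point on the log scale, while other forms were not tested. A fish whose kidney held an intermediate mix of cells would also give arithmetic means and stays open. If its RNA or reads were mixed, library 3 may not be an independent measure of 12 h, and without it 34 features are called at 12 h against 0 h.

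The third pattern is that kidney tubule and podocyte markers are lower at 12 h. A smaller share of renal RNA in the 12 h libraries would leave the levels of the 6 blood cell lists at or above those at 0 h, and no list was lower past the threshold in t tests over libraries: the monocyte list differed by -0.48 with a Bonferroni p of 0.0875, the thrombocyte list by -0.32 with 0.180 and the erythroid list by -1.09 with 0.588. The T and NK, B and neutrophil lists differed by 0.15, 0.05 and 0.13. With 3 libraries a group and control library 3 apart in the erythroid list, a smaller share of renal RNA cannot be told apart from a change within the cells after poly(I:C).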

How the results depend on the processing

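Averaging control libraries 1 and 2, leaving out 12 h library 3 as well, and keeping only fish matches were chosen only after the result was seen; the other alternatives were planned. Leaving out 1 library gave 34 to 876 called features at 12 h against 0 h, 0 to 78 at 48 h against 0 h, 29 to 1307 at 48 h against 12 h, 21 to 2337 over the 3 groups, 0 to 33 in the shared response and 33 to 39 lists past the threshold; fewer samples, and a spread estimated from fewer, are part of the cause by construction. Averaging the control pair gave 60, 438 and 110 at 12 h against 0 h, 48 h against 12 h and over the 3 groups, and with 12 h library 3 left out 3, 0, 0 and 3, counting 48 h against 0 h as the second; by limma the 0 counts at 48 h against 12 h and at 48 h against 0 h had 6784 and 2010 of 43850 features at an unadjusted p under 0.05, the second no more than unchanged groups would give. Limma without the trend gave 230, 0, 326 and 163 and a shared response of 0. The replicate number as a block gave 284, 3, 285 and 105, and whether the numbers pair samples was not settled. Residuals of libraries with the same number correlated between -0.098 and 0.152. Of the 9 libraries, 5 correlated best, among libraries of other groups, with a library of their own number. A filter of 5 TPM gave 1364 at 48 h against 12 h and 858 over the 3 groups, and features with a fish match alone 1559 and 949, with fewer features tested. Only the compared groups gave 250 at 12 h against 0 h; a pseudocount of 0.1 and summed features each gave 3 at 48 h against 0 h; adjusted p under 0.01 gave 61, 3, 35 and 42. Of the 35 list calls, 0 held with an estimated correlation and 19 lists passed by fry, 11 of them among the 35. Directions reversed for ribosomal proteins after quantile normalization at 48 h against 0 h (adjusted p 0.986) and at 48 h against 12 h (0.0135), and by fry at 48 h against 12 h for complement (0.0156) and for muscle, liver and gut (0.0447); the cause was not tested for these or for the other counts, except that fry does not compare a list with other genes and quantile normalization shifts the median of all features. Named features past the threshold kept their direction in every alternative run on them, and quantile normalization ended the call of 6 of 52 at 12 h and 7 of 50 at 48 h against 12 h. Limma without the trend ended the call of 34 of the 52, 32 of the 50 and all 5 at 48 h against 0 h. The replicate block ended that of 15 of the 52, 23 of the 50 and 2 of the 5. The planned tests on read counts and their size factors were not run, because the table holds none. With 1 read worth 0.59 to 0.78 TPM on a short feature, values of a few TPM rest on a few reads.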

Other observations

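The pathway tests were chosen only after the result was seen. Pathway names in the table's own annotation, tested against 4736 annotated genes in 812 tests, put the proteasome first. At 12 h against 0 h, 24 of the 62 annotated genes that rose belong to the 48 genes of that pathway (38.7% against 1.01%), with adjusted p 8.5e-32. At 48 h against 12 h, 11 of the 53 that fell do (adjusted p 7.8e-10). These tests take genes that move together as independent: the proteasome list had adjusted p = 0.0983 with an estimated correlation in either comparison, and 0 of its genes were called without 12 h library 3. Next, both at adjusted p 0.057 and so not past the threshold, came ascorbate and aldarate metabolism, with 4 of the 81 annotated genes that fell at 12 h, and ferroptosis, an iron-dependent form of cell death, with 5 of them (ftl, sat2, slc39a14, slc40a1 and steap3).

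Red cell and T cell genes were unevenly spread over the libraries in ways that the groups do not describe. The globin gene hbae stood at 5967, 5661 and 5453 TPM in the 12 h libraries and at 9138, 2164 and 4083 in the 48 h libraries, and cd3e at 58.2, 15.5 and 33.4 and at 68.4, 76.0 and 70.1. Skeletal muscle genes were seen in control library 3 and in 12 h libraries 2 and 3: mylpf stood at 27.8, 6.44 and 4.54 TPM there and at 0.39 or less in the other libraries. Uromodulin (umod), a product of the distal tubule, stood at 38.1, 96.8 and 65.2 TPM at 12 h and at 14.6, 3.34 and 2.22 at 48 h. These genes were chosen after their values were seen.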
